A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

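Total RNA was extracted with hot acid phenol from yeast in mid-log phase, about 20 µg per sample was converted to biotinylated cRNA, and each sample was hybridised to an Affymetrix yeast array, per the labels' protocols. The authors deposited 1 intensity value per probe set and array on a linear scale. MAS5 was used, per the submitters' processing notes. Its version, scaling target and detection calls are not given in the sources used here. The deposited intensity values were never below 0, and control probe sets were among them. No second scaling was applied in the main setting. Where arrays are scaled to a common level, a change shared by most genes is removed, and values near 0 have no stable ratio.

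The table held 9335 probe sets, of which 60 were controls. The platform annotation gave 6504 probe sets 1 gene symbol, 328 several symbols and 2443 none. All 6504 matched the R64 gene table, and 0 symbols needed an update. Where several probe sets named 1 gene (315 genes), the brightest stood for it, which left 5656 genes. Probe sets with several symbols or none were left out of the main test and tested apart with the same signal filter.

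Signals were converted to log2(signal + 5). The offset was 0.1 of the median signal of gene probe sets, 51.5, rounded to 1 significant digit, and fold changes on this scale understate the change of dim genes. The 25% of genes with the lowest mean were left out (mean log2 under 4.88, a signal of about 24.5), leaving 4242. Group differences, H2A K4,7G minus wild type, were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment at 0.05. The unpaired fit had 4 residual degrees of freedom. Tables were joined with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.

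Groups and replicate numbers came from the sample labels. The wild-type arrays also serve, per the labels, a second H2A mutant that was not analysed here. Whether equal numbers pair the samples was checked from the data: deviations from the group means correlated at 0.38, 0.59 and 0.80 between arrays numbered 1, 2 and 3. All 3 were above the preset bound of 0.1, so the fit with replicate number as a block (2 residual degrees of freedom) is given beside the unpaired fit. These 3 correlations and the counts of both fits were first seen together, and the bound itself was preset. The deviations of wild-type replicate 2 also correlated at 0.53 with mutant replicate 1, and those of wild-type replicate 1 at 0.30 with mutant replicate 2, so the main structure parted the third pair from the other arrays.

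Gene lists were written from general knowledge of yeast pathways. Of 42 lists, 39 had at least 3 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, whose p asks whether members move on balance one way. No list was called by either of these, with or without the block. A list of genes within 20 kb of a chromosome end used the R64 gene table, with the outermost gene taken as the right end. The symbol rule for ribosomal proteins first took in RPP1, an RNase P subunit, and was corrected after values had been seen. List medians were set against 10000 random lists matched on mean signal in 20 bins.

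The groups, tests, lists, alternatives and rule for named genes were fixed before the data were examined. The rule took genes past the unpaired test with non-overlapping groups or, with fewer than 5 of them, the 10 smallest unadjusted p-values. To these it added up to 4 members of each list past the set test and a panel of histone, marker and mating type genes. The 11 genes of the blocked fit were added after values had been seen. Alternatives covered the offset, the filter, quantile normalization, median centring, the variance model, an unmoderated two-sample test, the block, each array left out and all probe sets tested apart. Alternatives added after seeing the data were the third pair as a block, leaving out pairs, each choice combined with the block, and centring on the median of the tested genes. The measure used to compare a list across settings, its mean against the other genes, also replaced a median after values had been seen.

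The fits were tested on simulated data for this comparison, 10 simulations of 4242 genes with 200 changed. These were built on the residual spread of the blocked fit and on its estimated effects of replicate number. The unpaired fit recovered 1.7%, 63.4% and 98.9% of changes of 0.5, 1 and 2 on the log2 scale, and the blocked fit 88.9%, 100% and 100%. False genes among the calls were 0% and 6.1%. The blocked fit was the model behind the simulated data, so its higher recovery was built in. The recovery figures therefore do not show which fit suits the real arrays better. A list of 50 genes shifted by 0.2 was called in 10 of 10 simulations with the preset correlation and in 0 with the estimated one. Lists were simulated for the blocked fit only and with genes that varied independently, so a correlation between list members was not covered.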

Results

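Gene expression was measured in Saccharomyces cerevisiae carrying a histone H2A in which the lysines at positions 4 and 7 of the N-terminal tail are replaced by glycine (H2A K4,7G), and in a wild-type strain. Glycine cannot be acetylated, so the substitution removes 2 modifiable residues of the tail. The comparison asks which mRNAs depend on these residues. Each strain was represented by 3 Affymetrix arrays, 6 in all, hybridised with biotin-labelled cRNA made from about 20 µg of total RNA. The cells had been grown in rich glucose medium to mid-log phase (OD600 0.5 to 0.7). Median signals over gene probe sets ranged from 45.2 in wild-type replicate 2 to 59.25 in wild-type replicate 3. The number of arrays limits the precision, and p-values cover only the spread between these arrays, since the labels do not say whether replicates were separate cultures.

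Among named genes, differences between the strains were small. With the strains compared as unpaired groups, limma called 0 of 4242 genes. At an unadjusted p under 0.05 there were 165 genes, 130 higher and 35 lower, where 212 are expected by chance if arrays vary independently. Arrays of the same number deviated together, which widens the spread within each strain, so the lower count does not show fewer changes than chance. The smallest adjusted p was 0.832. With replicate number as a block, which removes variation shared by arrays of the same number, 11 genes rose in H2A K4,7G and 0 fell. Only ARG1 among them rose at least 2-fold. In that fit 634 genes were higher and 203 lower at an unadjusted p under 0.05, a balance that depended on scaling: it was 460 and 441 under quantile normalization, 386 and 498 under median centring, and 431 and 481 with centring on the tested genes. The blocked calls were 11 higher and 2 lower, 10 and 3, and 49 and 43 under the same scalings. They were 42 higher and 6 lower with the filter set by the negative controls, 7 and 3 with all probe sets tested apart, and 0 with an unmoderated test. With pair 1, 2 or 3 left out, 70, 99 and 201 genes were higher and 22, 15 and 25 lower.

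The 11 genes included enzymes of arginine, histidine and NAD synthesis. ARG1, which encodes argininosuccinate synthetase, had a signal of 107 ± 27.5 (SD, n = 3) in wild type and 223 ± 32.1 in the mutant. Its log2 difference was 1.05 ± 0.11 (SE), with an adjusted p of 0.00333 in the blocked fit. ARG4, the enzyme of the next step, rose by 0.75 (adjusted p = 0.00531), and HIS4, a multifunctional enzyme of histidine synthesis, rose by 0.82 (adjusted p = 0.00353). BNA2 and BNA1, enzymes of the kynurenine route from tryptophan to NAD, rose by 0.74 and 0.70 (adjusted p = 0.0292 and 0.0421). The uncharacterised YJR079W, which is the next gene after BNA2 on its chromosome in the R64 gene table, rose by 0.91. A second probe set for YJR079W had a mean signal of 8.1, too dim to bear on this.

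The other 5 genes had varied roles. PIR3, a cell wall protein, rose by 0.95 (adjusted p = 0.00531). NCA3 rose by 0.84 (adjusted p = 0.00606). GPD1, a glycerol synthesis enzyme induced by osmotic stress, rose by 0.71 (adjusted p = 0.0238). The uncharacterised YLR297W rose by 0.70. TPO2, a polyamine exporter, rose by 0.69, from a probe set that can cross-hybridise. All 11 genes were higher in the mutant in 3 of 3 pairs. In 7 of them, ARG1, HIS4, PIR3, ARG4, NCA3, BNA2 and YLR297W, every mutant array lay above every wild-type array. BNA2, YLR297W and YJR079W were dim, with wild-type means of 22.8, 19.9 and 28.2, and the highest negative control signal was 32.8, on mutant replicate 2.

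**Figure D1:**
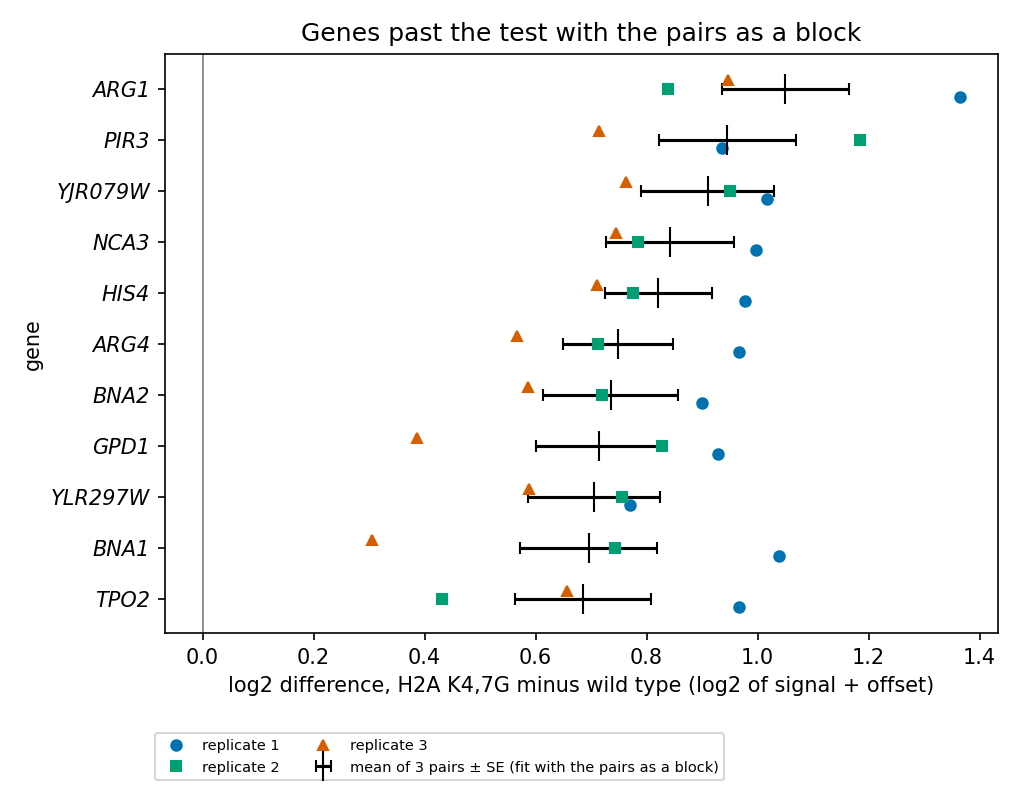
Log2 difference in signal between H2A K4,7G and wild type for the 11 genes past the test with the pairs as a block. Coloured points are the 3 replicate pairs, and black bars give the mean and SE of the blocked fit. All points lie to the right of 0, and ARG1 has the largest mean, 1.05.

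The unpaired comparison ranked several of the same genes first, none of them past its test. Its 10 smallest unadjusted p-values belonged to HIS4, NCA3, ARG1, ARG4, PIR3, YLR297W, CLN3, LOC1, BNA2 and ARG7. CLN3, a G1 cyclin, had a log2 difference of 0.49 and signals of 310 ± 22.3 and 436 ± 23.2. LOC1, a nuclear protein of ribosome assembly, had a difference of -0.51 and signals of 398 ± 44.0 and 277 ± 20.2. Both had an adjusted p of 0.0504 in the blocked fit. Groups did not overlap for 277 genes higher and 133 genes lower in the mutant, 9.67% of those tested. Chance gives 10% for exchangeable arrays, which these were not, as arrays of the same number deviated together, so the share is not a measure of change or of its absence.

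Genes of amino acid synthesis under general amino acid control were higher as a group. The 50 tested members had a median log2 difference of 0.19, with 43 higher and 7 lower (camera adjusted p = 4.09e-07; adjusted p = 0.276 with an estimated correlation). With the block, 3 members passed over all genes, and 18 rose and 0 fell when adjusted over the list alone. Without the block the counts were 0 and 3. ARG1, HIS4, ARG4 and ARG7 had the smallest p-values, and ARG7, an enzyme of ornithine synthesis, had a difference of 0.47.

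Sulphate assimilation and methionine genes were also higher as a group, with a median of 0.30 over 22 members (camera adjusted p = 6.41e-05; adjusted p = 0.511 with an estimated correlation). With the block, 10 rose and 0 fell when adjusted over the list alone, and 0 passed over all genes. The differences were 0.57 for MET3 (ATP sulfurylase), 0.48 for MET14 (adenylylsulphate kinase), 0.49 for MET5 (a sulphite reductase subunit) and 0.38 for CYS3 (cystathionine gamma-lyase). Common selection marker genes had a median of 0.28 over 10 members (camera adjusted p = 0.0108; adjusted p = 0.511 with an estimated correlation). That list shares 3 members with the amino acid list and 1 with the sulphur list. Its differences included 0.35 for MET17, 0.30 for HIS3 and 0.29 for LYS2, and 5 members rose with the block when adjusted over the list alone. Its adjusted p was 0.103 without wild-type replicate 3.

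Respiratory chain and ATP synthase genes had a median of 0.29, with 33 of 36 members higher (camera adjusted p = 5.35e-08; adjusted p = 0.984 with an estimated correlation). With the block, 22 rose and 0 fell when adjusted over the list alone, while 0 passed over all genes. Differences were 0.46 for COX8, 0.51 for NDI1, 0.38 for ATP2 and 0.31 for QCR2, members of cytochrome oxidase, the internal NADH dehydrogenase, ATP synthase and the cytochrome bc1 complex.

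Mitochondrial ribosomal protein genes had a median of 0.15, with 55 of 65 members higher (camera adjusted p = 0.00399; adjusted p = 0.984 with an estimated correlation). The differences were 0.40 for MRPL38, 0.41 for MRPL8, 0.37 for MRPL9 and 0.30 for MRP7, and 0 members passed with the block when adjusted over the list alone. Genes of the TCA and glyoxylate cycles and acetate use had a median of 0.21 over 20 members (camera adjusted p = 0.049; adjusted p = 0.984 with an estimated correlation). With the block, 6 rose and 1 fell when adjusted over the list alone. ADH2, which oxidises ethanol, and ACO1 (aconitase) had differences of 0.45 and 0.29, YAT1 had 0.29, and ATO3, a membrane protein linked to ammonium export, had -0.37. Genes induced in the general stress response had a median of 0.23 over 28 members. Their camera adjusted p was 0.189 without the block and 0.000638 with it (adjusted p = 0.84 with the block and an estimated correlation). Without the block it was 0.0454 under quantile normalization and 0.0302 under median centring. Without mutant replicate 3, the adjusted p was 0.49 for the mitochondrial ribosome list and 0.424 for the TCA list, and without wild-type replicate 2 it was 0.25 for both.

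The 83 nucleolar rRNA processing and assembly genes had a median of -0.12, with 63 lower and 20 higher (camera adjusted p = 3.07e-11; adjusted p = 0.984 with an estimated correlation). No member passed over all genes or over the list alone, and 19 were lower and 0 higher at an unadjusted p under 0.05 in the blocked fit. Differences were -0.39 for UTP7, -0.50 for UTP4 and -0.32 for IMP3, components of the small-subunit processome, and -0.33 for RRP8, an rRNA methyltransferase. The list's mean against the other genes was -0.18 with all arrays and -0.04 without mutant replicate 3, where its adjusted p was 0.424.

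Cytosolic ribosomal protein genes had a median of -0.07 over 80 members (camera adjusted p = 0.000163; adjusted p = 0.984 with an estimated correlation), but this call was lost under quantile normalization (adjusted p = 0.436) and median centring (adjusted p = 0.0992). The mean of the list against the other genes was -0.12 in the deposited scaling, -0.12 under median centring, which cannot alter it, and -0.03 under quantile normalization. The list medians were -0.19, -0.11 and 0.08 in the pairs numbered 1, 2 and 3. RPS1B, from a probe set that can cross-hybridise, and RPL22B had differences of -0.27 and -0.21, and RPL39 and RPS14B had 0.36 and 0.30. The 18S rRNA control signal of the mutant over wild type was 0.753, 0.572 and 1.01 in those same pairs, and the 25S signal 0.766, 0.484 and 0.926. Within wild type alone the 25S signal was 126, 296 and 21.4 on replicates 1, 2 and 3, so these ratios do not measure rRNA levels. A link to the ribosomal protein list was not tested.

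**Figure D2:**
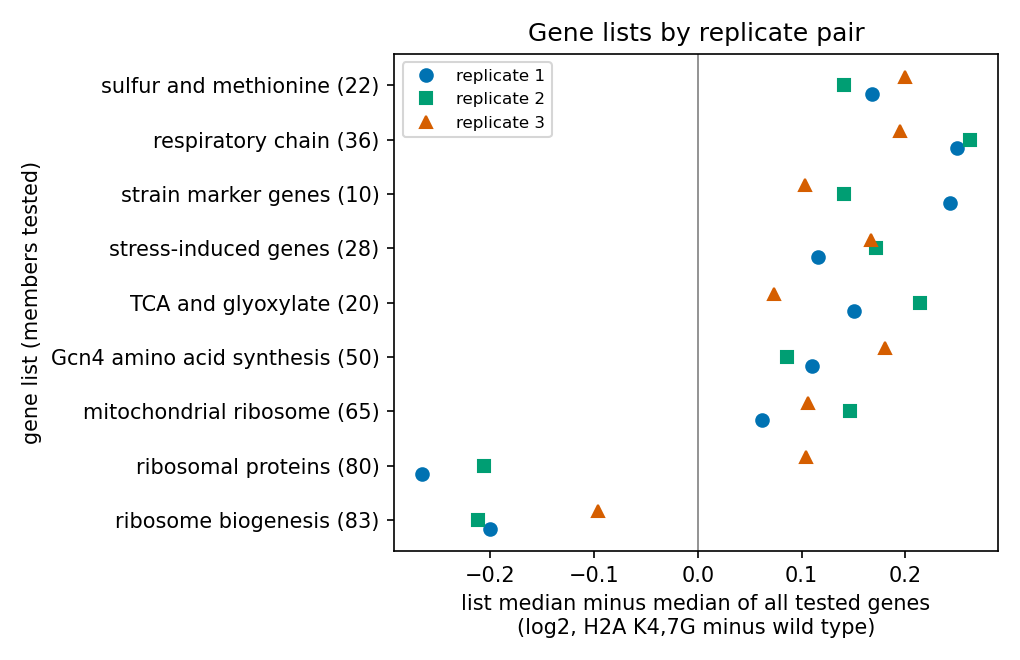
Median log2 difference between H2A K4,7G and wild type of each gene list past the set test in either fit, minus the median of all tested genes, by replicate pair. The ribosomal protein list lies below 0 in replicates 1 and 2 and above 0, at 0.10, in replicate 3, and the other 8 lists have the same sign in all 3.

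Neither the histone list, with 4 tested members, nor the lists of MATa and haploid markers passed the set test. The list of alpha-cell markers had fewer than 3 tested members, so no set test was made for it. No probe set named HTA1 or HTA2 alone, as the 2 H2A probe sets each carry 2 gene symbols, so the level of the altered gene by itself was not analysed here. Of the 233 probe sets with several symbols above the signal filter, 0 passed in either fit. A substitution of codons need not alter the mRNA level in any case, so these arrays do not check the strain labels. HTB1, encoding H2B, had signals of 1373 ± 160 in wild type and 1327 ± 50.2 in the mutant. The other H2B gene, HTB2, lay between 0.7 and 8.2 on all 6 arrays of both strains, under the signal filter. Why its signal was that low was not tested. The MATa pheromone genes MFA1 and MFA2 had differences of 0.03 and 0.02, and the receptor gene STE2 had -0.01. The MFA1 probe set can cross-hybridise, and a second, dimmer one showed -0.39. The alpha-factor gene MF(ALPHA)1 lay between 16.7 and 22.9 on all 6 arrays, under the signal filter. Among the mating genes AFB1 had -0.52, STE6 0.51, FAR1 0.45 and SAG1 0.41, none past either test over all genes. ACT1 (actin) had -0.05, URA3 -0.10 and GCY1, an aldo-keto reductase, 0.21.

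No call was made for 30 of the 39 lists in either fit. Histone, phosphate starvation, galactose, heat shock, glycolysis, cell wall, proteasome and NuA4 genes were among them, as were genes within 20 kb of a chromosome end, with a median of 0.07 over 70 members (camera adjusted p = 0.942). NAD synthesis genes as a list had a median of 0.06 (camera adjusted p = 0.605), although BNA2 and BNA1 belong to it.

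The arrays numbered 3 stood apart from the rest. The first principal component held 66.0% of the variance and placed both replicate 3 arrays at 18.2 and 18.6, against -14.1 to -4.51 for the other 4. Hybridisation spike-in signals were 2.36 times lower in wild-type replicate 3 and 2.04 times lower in mutant replicate 3 than in the other arrays of their strain. The 25S rRNA controls were 9.88 and 6.07 times lower and the 18S controls 5.95 and 3.76 times lower. The ratio of 3' to 5' signal, a sign of RNA quality, was 2.10 and 2.21 times higher for the control YER022w, 1.20 and 1.24 times for YER148w, and 0.978 and 1.03 times for YFL039C. In the mutant over wild type, the YER022w ratio was 1.28, 1.05 and 1.22 in the 3 pairs, the YER148w ratio 0.873, 0.907 and 0.916, and the YFL039C ratio 1.06, 0.987 and 1.08. Without both replicate 3 arrays, the unpaired comparison called 60 genes higher and 2 lower.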

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

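The test of array sensitivity and the search for further probe sets were chosen after the results were seen. Probe sets without a gene symbol in the annotation used here lay outside the main comparison, and 6 of them passed with the block. Probe sets 3954_at, 3952_at and 3953_at also passed without it. Their wild-type signals were 240 ± 56.9, 195 ± 41.8 and 201 ± 92.8 (SD, n = 3), and the mutant signals were 0.5, 0.567 and 0.367. The log2 differences on the offset scale were -5.45, -5.16 and -5.17. The 95th percentile of the 13 negative control probe sets was 16.9, 23.9 and 4.4 on mutant replicates 1, 2 and 3. In the pair with the lowest ratio, pair 2, the wild-type signals were 9.46, 7.59 and 6.27 times that floor.

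A search of all probe sets, made after these were seen, found 5 with every wild-type array over 10 times every mutant array (mutant signals under 1 taken as 1), and 0 in the reverse direction. All 5 were without a symbol, and their numbers were consecutive, from 3951_at to 3955_at. The 2 added by this search were 3951_at, with signals of 74.3 ± 24.6 in wild type and 2.07 ± 0.55 in the mutant, and 3955_at, with 17.0 ± 4.83 and 0.5 ± 0.3. The floor is a high bound, as the median negative control signal was 1.8, 1.9 and 1.7 on mutant replicates 1, 2 and 3. In wild type, 3951_at lay at 2.33 times the negative control floor in its lowest pair, and 3955_at lay under the floor in 2 of 3 pairs. Probe sets 3951_at to 3954_at lay between 23.2 and 69.95 times the floor in pair 3, and 3954_at at 11.3 times in pair 1. All other values were below 10. Against that floor a 10-fold loss in every pair is therefore shown for none of the 5. A lower sensitivity of the mutant arrays would bring other probe sets of the same wild-type level down as well. Among 4689 of them, 3 lay at or below that negative control level on all 3 mutant arrays, which argues against it. A sequence present in the wild-type strain and missing from the mutant strain may account for the loss, apart from any effect of the histone change. Neither was tested, and the genes these probe sets measure were not named here.

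The remaining probe sets were higher in the mutant with the block. Probe set 10872_at had a log2 difference of 0.85, with signals of 110 ± 26.6 and 202 ± 50.7. Probe set 10902_at had 0.80, with 192 ± 15.7 and 337 ± 14.4, and another had 0.76, with 105 ± 24.4 and 180 ± 35.3.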

How the results depend on the processing

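Tests of the third pair, of left-out pairs, of the block joined to another choice and of centring on the tested genes were chosen after the data were seen. The unpaired count of 0 genes, and of 0 at 2-fold, was the same under each offset, filter, scaling, variance model and test, and from 0 to 0 when 1 array was left out. It was 11 (1 at 2-fold) with the replicate block, 14 (1) with the third pair as a block and 62 (4) without both arrays of replicate 3. The replicate block also brought in the stress list and changed no other list call. The blocked count of 11 genes became 6 with a stricter filter on level (2828 genes tested), 48 above the negative controls, 92 with median centring on the tested genes (49 higher, 43 lower) and 0 with the unmoderated test, where 2 residual degrees of freedom remain. It ranged from 92 to 226 when 1 pair was left out. The single gene at 2-fold became 3 with no offset and 0 with an offset 5 times as large, quantile normalization, either median centring or the unmoderated test, and ranged from 1 to 5 when 1 pair was left out, with 0 higher and 1 lower without pair 1, 4 and 0 without pair 2 and 4 and 1 without pair 3. The cause was not tested. Of the 11 genes, 9 were kept under quantile normalization, 10 under median centring, 11 on the tested genes' median, 9 with the larger offset, 6 with all probe sets tested apart (7 probe sets higher and 3 lower in all) and 11 without the third pair. Of 8 still tested under the stricter filter, 6 were kept.

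The 8 lists ranged from 4 to 10 when 1 array was left out, with 5 without wild-type replicate 2 and 4 without mutant replicate 3. Leaving out 1 array also gives replicate 3 an unequal share in the groups, so these losses cannot be told from that imbalance. Without both arrays of replicate 3, 9 lists were called, 7 higher and 2 lower: the same 8 and the stress list (adjusted p = 0.0421). Estimated correlation and fry gave 0 lists, with and without the block; in simulations the estimated correlation missed a shift of 0.2 in each of 10 runs. The ribosomal protein list ranged from -0.37 to 0.0276 relative to other genes when 1 array was left out. It reversed to 0.02 without wild-type replicate 2 and 0.0276 without mutant replicate 3, and was lost without wild-type replicate 1 (adjusted p = 0.951). The TCA list was lost without wild-type replicate 1 (adjusted p = 0.236) and with no filter (adjusted p = 0.0672). Over 71 named genes and 1408 alternative values, 1372 stayed uncalled, as all 71 genes were in the unpaired fit. The other 36 values passed only in an alternative, and 0 were reversed. With no call to lose, this tally is not a measure of stability. Meanwhile 13 genes past no test changed sign. Over 9 lists and 153 values, 100 were the same, 43 weaker, 8 stronger and 2 reversed. Dim genes limit the rest: the 13 negative controls reached 32.8 on mutant replicate 2, above the wild-type means of BNA2 (22.8), YLR297W (19.9) and YJR079W (28.2).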

Other observations

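Genes of other lists are given here as values. Among stress-induced genes with the block, HSP104, a disaggregase, had a log2 difference of 0.54, GLK1 (glucokinase) 0.50, GAD1 0.52 and UGP1 0.39, while the chaperone gene SSA4 had -0.43. When adjusted over the list alone, 6 of 28 rose and 1 fell. In the glycolysis list 5 of 20 rose in that way, among them GPD1, which also passed over all genes, TDH1 (0.50), PDC5 (0.47) and ENO1 (0.33), whereas the abundant TDH3 had -0.28 and was lower in 2 of 3 pairs. BNA5 and BNA3 of the kynurenine pathway each had 0.41. These genes were picked after their values were seen. Over all tested genes, 1169 were higher and 629 lower in every pair, or 42.4%. Chance gives 25% only where rises and falls are equally likely and the pairs are independent. The median gene differed by 0.08, 0.10 and -0.02 in pairs 1, 2 and 3, so the share is not a measure of change.

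Technical explanations were weighed for the 8 lists. Under quantile normalization, which can alter the shift of a list against other genes, and under median centring, which cannot, 7 of the 8 kept their direction and call, which argues against scaling for those 7. Of the 8 medians, 0 lay inside the central 95% of random lists matched on mean signal, which argues against a compression tied to signal level as their only source. That range is no test of the lists themselves. They had been picked as extreme against the other genes of the same arrays, and random lists lack the variation that list members share. The third pair and the mean of the other pairs both had the direction of the pooled test in 7 of the 8. This was partly built in, as the lists were picked on the pooled values. Without both replicate 3 arrays, the unpaired fit called 9 lists, 7 higher and 2 lower, with the 8 among them. That argues against the third pair as the only source of the calls. The ribosomal protein list was the exception in the scaling check and in the direction of the pairs. Its mean against other genes went from -0.12 to -0.03 under quantile normalization, and relative to all genes its median was -0.23 in pairs 1 and 2 and 0.10 in pair 3, so scaling stays open for that list. For the other 7, variation that list members share across these few arrays stays open. None was called with an estimated correlation or by fry, but that loss does not show shared variation. In simulations of the blocked fit with independent genes, the estimated correlation called 0 of 10 true shifts. Its estimates without the block ran from -0.018 for the marker list to 0.613 for the respiratory list. The amino acid list was lost at 0.0158, near the preset 0.01. A coordinated effect of the H2A substitution, a difference in growth state between cultures and a strain difference stay open too. None of these causes was tested.

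Rises were 75.7% of genes at an unadjusted p under 0.05 in the blocked fit, 51.1% under quantile normalization and 47.3% with centring on the tested genes. These scalings set the balance of rises and falls near even by construction, so they do not decide whether the excess came from the cells or from the array levels. The 11 genes stayed higher under both.

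The splits of the arrays are too few for a share under 0.05. In the unpaired fit the real split gave 0 genes, and so did all 10 splits, with a highest other of 0. Of the 4 splits that part all 3 pairs, 1, the real one, gave as many as 11 genes, and the highest of the others was 0.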
